A study of Mus musculus with 6 samples.

How the data were processed

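A total of 6 droplet libraries of dissociated mouse uterine tube were analysed, 3 from the distal section and 3 from the proximal section. Per the labels' protocols, tubes of groups of adult C57BL6 females in estrus were divided into a distal and a proximal section, the tissue of a section was combined across the mice of a group, and it was digested with collagenase and hyaluronidase, TrypLE and Dispase II, strained, depleted of dead cells and loaded for 10x Genomics Single Cell 3' v2 libraries. A library therefore pools several mice, and the number of mice per library was not analysed here. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, 1 matrix per library, with no normalization. The submitters' processing notes name Cell Ranger 6.1.2 and the mm39 build, whereas the file headers name Cell Ranger 7.0.0. The values themselves showed that every listed barcode held at least 500 UMIs and that the libraries had not been pooled or scaled. No genome coordinates are printed, because the annotation at hand was built on GRCm38.

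Libraries are named by their region and by the number in their title, which runs over 1, 2 and 3 for distal and 2, 3 and 4 for proximal. A second number in the labels' descriptions runs over 1, 2 and 4 for distal and 2, 3 and 4 for proximal, so both pair distal 2 with proximal 2 and differ for the others. The region comparisons used no pairing, and fits with a term for group 2 were added. The matrices listed 50559 genes and 20731 barcodes with 91560090 UMIs. Per-library totals ran from 426707 UMIs in proximal 3 to 32488145 in distal 1. Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs, which removed 1447 barcodes. Doublets were scored per library against simulated doublets (the Scrublet method, rewritten in Python), and the highest-scoring 0.8% per 1000 barcodes were removed, 818 barcodes in all. The remaining 18466 cells were scaled to 10000 counts and log1p transformed. They were clustered on 2000 variable genes, 30 principal components and 15 nearest neighbours with the Leiden method (resolution 1, seed 1) and no integration of libraries. Fixed-list, mitochondrial, ribosomal and haemoglobin genes were left out of the variable genes. Epithelial clusters were taken out and clustered again with 20 components.

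A cluster took the name of the cell class whose marker genes had the highest mean score. The score was the log2 of CPM plus 5, minus its mean over clusters, so it is a log2 difference. CPM are counts scaled to a common total per library or cluster. Levels given with the tests of regions or clusters are edgeR's cpm. Marker levels and cluster scores were scaled from the summed counts alone. The score had to reach 1.5, at least 3 markers had to be detected in at least 20% of the cells, and another class could not have more markers among the 10 leading genes. Of 28 clusters, 3 met no name. Inside the epithelium (14 clusters, written E1 to E14), clusters were assigned to the ciliated class or named by their nearest class where the rule was not met. Marker lists, 16 gene lists with 512 symbols, the tests, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Through gene synonyms, 508 of the 512 symbols were matched to the matrices.

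Counts were summed per library and class, and a library entered with at least 10 cells of the class. Proximal was compared with distal by the quasi-likelihood test of edgeR 4.0.16 with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the Benjamini-Hochberg adjustment at 0.05. Fold changes are given as log2 of proximal over distal with their standard error. Levels are means of CPM over libraries with the standard deviation (SD). For a gene with no counts in a group, the fold was computed against 3 counts over the group and is a lower bound. For 1 to 3 counts the ratio of pooled CPM is given with its exact 95% counting interval. These bounds and intervals cover counting error only. Lists with at least 5 tested members were tested with limma 3.58.1 by camera (inter-gene correlation 0.01, and again with an estimated correlation) and by fry, whose p asks whether the genes of a list move one way on balance. List members were also adjusted over the list alone, meaning over all fixed-list genes of a class together. Shares of cells were compared by two-sided exact permutation tests. With 3 libraries against 3 the smallest p these can give is 0.1. Epithelial clusters of the 3 distal libraries were compared with the library as a block, and only fixed-list genes are named, because these had not been used for clustering. They can still vary together with the genes that were used, and the clusters compared were chosen by their marker scores. These comparisons therefore describe the clusters, and their p-values are not independent evidence that the clusters differ.

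The genes named in a region comparison are the 8 with the largest fold change in each direction that passed the adjusted test, had a mean log2 CPM of at least 4 and had no overlap between the regions, leaving out predicted, ribosomal and mitochondrial genes, and up to 2 members of each list with the smallest p that passed when adjusted over the list alone. The state comparisons name up to 2 members of each list. Some genes that met these rules are not named in the text or drawn in the figures. A fixed set of 10 marker and tumour genes is given with its levels. Symbols are those of the matrices.

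The alternatives chosen then were DESeq2 1.42.0 in place of edgeR, its RLE size factors, no low-count filter, blocks by title or description number, each library left out in turn, at most 10% mitochondrial UMIs, at least 500 genes per cell, no doublet removal, Leiden resolutions of 0.5 and 2, at least 20 cells per library and class, and a free RNA filter that left out genes below 10% of their level in the highest class. Chosen after seeing the data were an assignment of haemoglobin-led clusters to the epithelium, tests within 1 cluster shared by the regions, distal sums thinned to the proximal median depth (seed 7), both group 2 libraries left out and a term for group 2. The tests were run on simulated data (seed 11) with the same libraries and cell numbers and 200 genes changed. At a 4-fold change the region fits recovered 16.3% of changed genes in non-ciliated epithelium, 26.9% in ciliated epithelium, 75.2% in fibroblasts and 24.2% in smooth muscle. Over all calls of these fits, 2 of 17, 0 of 27, 9 of 90 and 1 of 24 were false. At a 2-fold change recovery was 0%, 2.1%, 5.4% and 1%. The block fits between epithelial clusters recovered 89.1%, 94.7% and 91.8% at 4-fold, and 9 of 134, 10 of 143 and 8 of 157 of their calls were false. Other tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and the data.table package (1.17.8). Other classes are given as shares only. Pericytes, lymphatic endothelium, mesothelium and myeloid cells had too few proximal cells for a test, and blood endothelial cells and T and NK cells had enough but no comparison of them was run.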

Results

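The data are single-cell expression profiles of the adult mouse uterine tube (oviduct), collected as 3 libraries of the distal section, which lies toward the ovary, and 3 of the proximal section, which lies toward the uterus. Each library pooled the tissue of a group of mice. The distal libraries held 7371, 4656 and 6034 barcodes with medians of 3329, 4580.5 and 2895.5 UMIs. The proximal libraries (numbered 2, 3 and 4) held 1189, 327 and 1154 barcodes with medians of 3666, 733 and 1081 UMIs. After filtering, 6652, 4115 and 5417 distal cells and 824, 325 and 1133 proximal cells remained. The comparisons asked which cell classes each section held, how the sections differed within a class, and how epithelial clusters differed from one another.

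Epithelial cells, which line the tube and secrete or beat toward the lumen, made up 35.9% ± 6.41 (SD, n = 3) of distal and 26.9% ± 10.3 (n = 3) of proximal cells. Fibroblasts of the tube wall made up 44.8% ± 11.9 and 46.7% ± 6.69. Smooth muscle made up 10.2% ± 7.92 and 4.33% ± 4.47, and proximal 2 had 0 of 824 such cells, which allows a share of up to 0.364%. Among epithelial cells, the ciliated class (clusters E2, E4, E7 and E12) made up 33.2% ± 7.25 in distal and 10.3% ± 5.77 in proximal libraries. The distal libraries had ciliated shares of 27.1%, 31.2% and 41.2%. The proximal libraries had 7.77%, 6.32% and 16.9%, so the ranges did not overlap. T and NK cells made up 1.37% ± 1.04 of distal and 9.56% ± 4.62 of proximal cells, and mesothelial cells 0.32% ± 0.284 and 2.12% ± 1.97. Pericytes made up 0.996% ± 0.816 and 0.14% ± 0.126, and blood endothelial cells 2.59% ± 1.73 and 5.11% ± 4.96. Lymphatic endothelial cells made up 0.258% ± 0.082 and 0.701% ± 0.507, and myeloid cells 0.487% ± 0.247 and 0.39% ± 0.367. Cells in clusters that met no name made up 2.75% ± 0.69 of distal and 4.07% ± 1.53 of proximal cells. Epithelial cluster E10 made up 0.655%, 2.48% and 8.42% of distal epithelial cells. In the proximal libraries it made up 0 of 296 cells, which allows up to 1.01%, 0 of 95 cells, which allows up to 3.16%, and 1.13% in proximal 4.

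None of the 5 share differences passed in the exact permutation test. In two-sided exact permutation tests of 3 libraries against 3, where the smallest p is 0.1, the ciliated share gave p = 0.1 (difference of -22.8 percentage points, adjusted p = 0.5). The same exact test gave cluster E10 p = 0.2 (-3.47 points), the epithelial share p = 0.4 (-9.01 points), smooth muscle p = 0.5 (-5.82 points) and fibroblasts p = 0.9 (1.90 points). In edgeR on the cell numbers the ciliated share fell by 1.67 on the log2 scale (adjusted p = 0.059) and E10 by 3.36 (adjusted p = 0.208). With the title number as a block the ciliated share fell by 2.22 (adjusted p = 0.0158). Only title numbers 2 and 3 hold a library of each region, so this block fit rests on them. It leaves little from which to estimate the spread. E10 was fitted at -8.40 there (adjusted p = 0.029), but proximal 2 and 3 had 0 such cells, so its fall has no exact size. The numbers in the labels are in accord for group 2 alone. The proximal libraries were both smaller and, apart from proximal 2, shallower. The fibroblast difference changed sign to -3.10 points without distal 1 and -1.69 points without proximal 4.

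**Figure D1:**
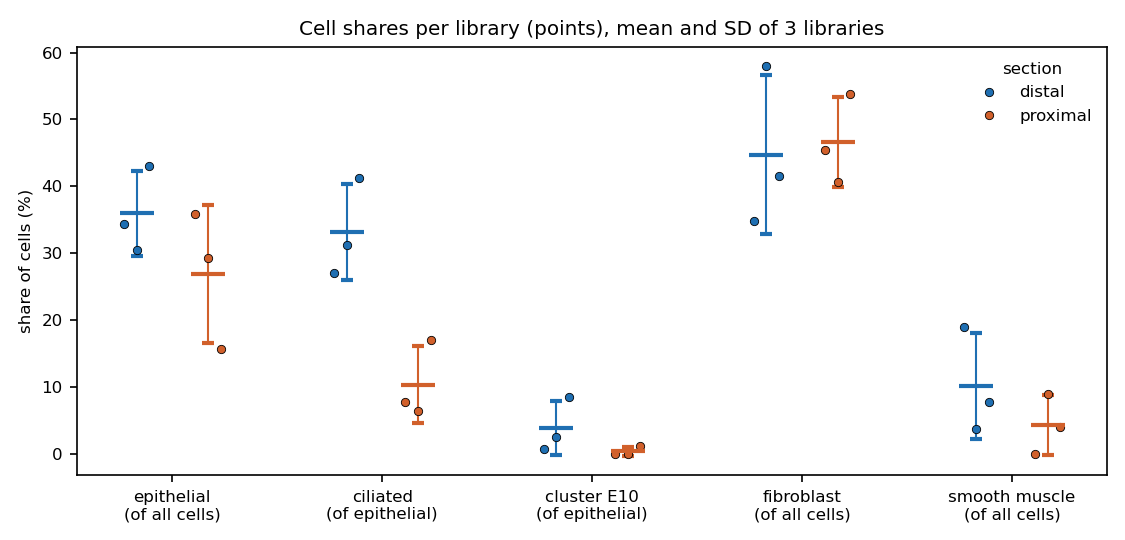
Share of cells in percent (vertical axis) of 5 classes in the 3 distal and 3 proximal libraries, with points for single libraries and bars for the mean and SD. The ciliated share of epithelial cells ran from 27.1% to 41.2% in distal and from 6.32% to 16.9% in proximal libraries.

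In non-ciliated epithelium the largest rise among the named genes was in Crabp2, which encodes a retinoic acid binding protein. It rose by 8.34 ± 0.67 (log2 fold change ± SE, 3 libraries against 3), from 0.213 ± 0.12 CPM (mean ± SD) in distal to 78.7 ± 41.6 CPM in proximal libraries. Urate oxidase, Uox, rose by 6.89 ± 0.53 on the log2 scale, and Serpina1e, of the alpha-1-antitrypsin family, rose by 6.73 ± 1.09, from 6.1 ± 6.96 to 658 ± 195 CPM. Penk, the precursor of the enkephalin peptides, rose by 6.63 ± 1.06 to 589 ± 427 CPM. Further rises were those of Naip5 (6.70 ± 0.71), a cytosolic sensor of bacterial flagellin, and of the Wnt ligand Wnt7a (6.57 ± 0.92). The leptin receptor Lepr (5.79 ± 0.94) and the mitochondrial translation factor Taco1 (5.73 ± 1.19) rose as well. The noradrenaline transporter Slc6a2 had 1593 distal and 3 proximal counts, a pooled proximal to distal ratio of 0.0299 (95% counting interval 0.00616 to 0.0875). Dcpp2, a secreted protein of the demilune and parotid family, fell by 6.24 on the log2 scale (SE 1.04), from 512 ± 192 to 6.07 ± 10.5 CPM. Lgr6, a receptor for R-spondins, had 733 distal and 0 proximal counts and was at least 15.4-fold lower in proximal libraries. Pooled ratios of other genes with few proximal counts were 0.0187 (0.000472 to 0.104) for Fam13a and 0.0313 (0.00645 to 0.0916) for the muscarinic receptor Chrm3. They were 0.0363 (0.00748 to 0.106) for mesothelin, Msln, and 0.0373 (0.00451 to 0.135) for the calcium binding protein S100a3. Pde4b, which degrades cyclic AMP, fell by 4.51 on the log2 scale (SE 0.79), from 447 ± 145 to 19.9 ± 16.1 CPM. These 16 genes had edgeR adjusted p between 0.000721 and 0.0344.

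The interferon response list of non-ciliated epithelium had a median log2 fold change of 0.64 over 21 tested genes. Of these, 3 rose over all genes and 7 when adjusted over the list alone, with Ifit3 at 3.40 ± 0.67 and Ifi44 at 3.05 ± 0.53. The camera test placed the list above other genes (adjusted p = 0.000156, but adjusted p = 0.544 with an estimated correlation). The extracellular matrix list had a median of -0.67 over 24 genes, with 1 rise and 4 falls over all genes and 2 and 6 adjusted over the list alone. Among its members the matrix protein Sparc fell by 3.14 on the log2 scale (SE 0.66), and the crosslinking enzyme Loxl1 had a pooled ratio of 0.0846 (0.0102 to 0.308). Camera gave this list adjusted p = 0.0494, and adjusted p = 0.544 with an estimated correlation. No other list passed camera in this class.

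In the retinoic acid list (10 genes, median 0.36) 1 gene rose and 1 fell over all genes and 3 rose and 3 fell adjusted over the list alone. Crabp2 was among its rises. The BMP and TGF-beta list (20 genes, median -0.42) had 3 rises over all genes, and 3 rises and 3 falls adjusted over the list alone. Its Id1 and Id3, which block helix-loop-helix factors, rose by 3.21 ± 0.40 and 1.98 ± 0.35. In the Hox and duct patterning list (18 genes) the median was 0.04, the mean -0.30 and the camera direction down (adjusted p = 0.514). There, 1 gene fell over all genes, the nuclear receptor Nr2f1 (fell by 3.12, SE 0.59). Adjusted over the list alone 2 rose and 2 fell, Hoxb8 among the rises (1.56 ± 0.38). The Wnt list (28 genes, median -0.02, camera direction up) had 2 rises and 1 fall over all genes and 4 and 3 adjusted over the list alone, with Wnt11 at 4.34 ± 0.79. In the Notch list (15 genes, median 0.22) 1 gene rose over all genes, the ligand Dll4 (2.83 ± 0.55), and 2 adjusted over the list alone, the other being the target gene Hey1 (1.08 ± 0.33). The progesterone receptor Pgr rose by 1.68 ± 0.37, from 28.6 ± 2.84 to 92.4 ± 25.9 CPM, alone among the 16 steroid hormone genes (median 0.05) by either adjustment.

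Ion transport (21 genes, median -0.005, mean 0.34) had 2 rises over all genes and 3 rises and 2 falls adjusted over the list alone. The sodium pump regulator Fxyd4 (5.40 ± 0.52, from 25.9 ± 7.14 CPM) and the pump subunit Atp1b1 (2.89 ± 0.48, from 48.3 CPM to 358 ± 158) were its rises. Antimicrobial defence (18 genes, median -0.87) had 2 rises and 1 fall over all genes and 2 and 2 adjusted over the list alone. The protease inhibitor Wfdc1 fell by 3.84 on the log2 scale (SE 0.70). The stress and immediate early list (31 genes, median -0.21, mean 0.22, camera direction up) had 2 rises over all genes and 4 adjusted over the list alone. Its metallothionein Mt2 rose by 4.64 ± 0.78, from 105 ± 68.3 to 2620.5 ± 1569 CPM, and its heat shock gene Hspa1b by 2.95 ± 0.61. The p53 target list (23 genes, median 0.20) had 0 rises and 1 fall over all genes, the receptor Eda2r (fell by 3.19, SE 0.69). Adjusted over the list alone it had 1 rise, Tnfrsf10b (1.93 ± 0.50), and 1 fall. The ovarian carcinoma list (42 genes, median 0.13) had 1 rise by either adjustment, cyclin D2, Ccnd2, at 4.92 ± 0.40. The cell cycle list (10 genes, median 0.55) had 1 rise by either adjustment, the chromatin protein Hmgb2 at 2.12 ± 0.43. The prostaglandin list (13 genes, median 0.09) had 0 calls over all genes in edgeR (2 by DESeq2 and 2 at an unadjusted p under 0.05) and 1 rise adjusted over the list alone, the cyclooxygenase Ptgs2 (1.91 ± 0.59). The axonemal list (12 genes, median -0.44) had 0 calls by either adjustment in edgeR and 0 by DESeq2, with 1 gene at an unadjusted p under 0.05.

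**Figure D2:**
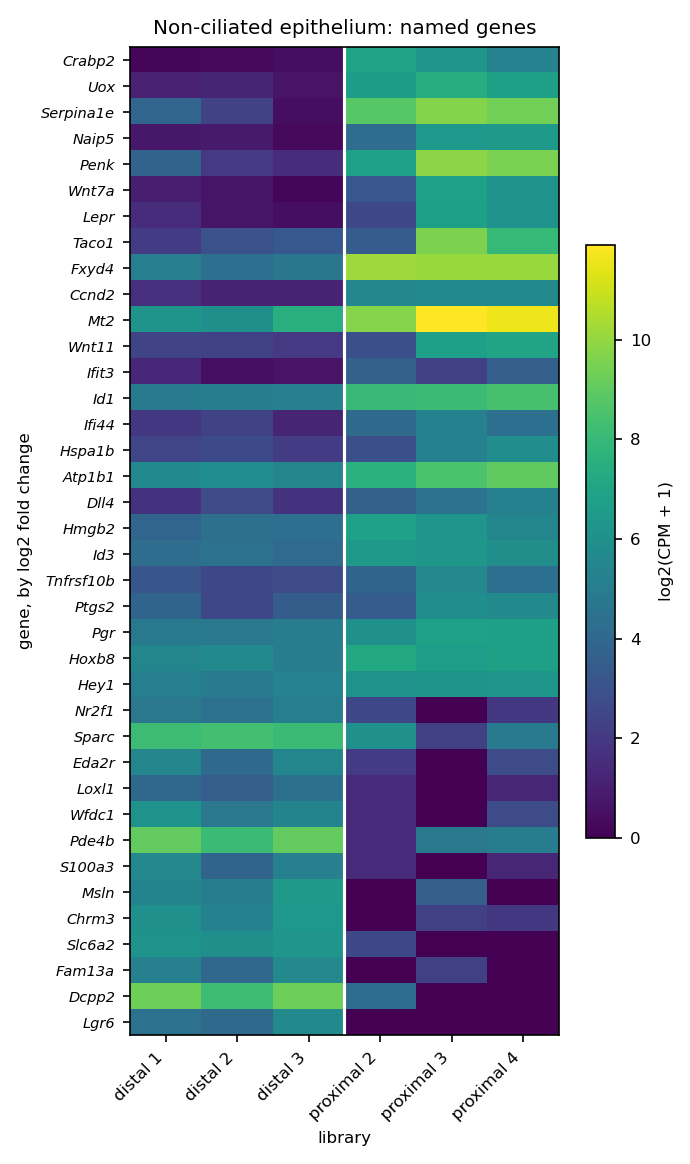
Heatmap of log2 of CPM plus 1 for the named genes of non-ciliated epithelium (vertical axis) in each of the 6 libraries (horizontal axis). Crabp2 averaged 0.213 CPM in the distal and 78.7 CPM in the proximal libraries.

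In all, 400 of 12754 genes passed in non-ciliated epithelium (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1640, 823 and 1153 distal and 273, 88 and 142 proximal cells). Of these 295 rose and 105 fell. An unadjusted p under 0.05 was reached by 2187 genes and DESeq2 called 1491. Distal 2 and proximal 2 departed together from the other libraries. With a term for this pair 1507 genes passed, 807 up and 700 down. Between these libraries alone the folds were smaller than those given for Taco1 (0.54), Hspa1b (0.29), Wnt11 (0.68), Dll4 (0.96), Ptgs2 (0.95), Lepr (2.35) and Wnt7a (3.04). Ptgs2 stood at 9.93 CPM in proximal 2, inside the distal range of 4.92 to 13.5 CPM. Different clusters held much of each region. Cluster 22 of the whole data (E11 in the epithelium) held 83 and 81 cells of proximal 3 and 4 against 7 distal cells, and cluster 24 (E13) held 93 cells of proximal 2 against 9 and 3 cells of distal 1 and 2. Serpina1e, Fxyd4, Crabp2, Naip5, Taco1, Lepr, Penk and Id1 were among the leading genes that define these clusters. Dcpp2 was a leading gene of distal clusters 7 and E3, and Slc6a2 and Msln of distal cluster 9. Within cluster 4, which held cells of both regions, 44 genes passed, and the sign turned for Pgr (-0.47) and Hey1 (-0.83). The number of calls was 7 without distal 1, 18 without distal 2, 6 without distal 3, 3204 without proximal 2, 35 without proximal 3 and 217 without proximal 4. It was 111 with distal sums thinned to the proximal depth. Msln, Lgr6 and Lepr stood at 3.41%, 7.71% and 8.37% of their level in mesothelial, smooth muscle and blood endothelial cells, a level that free RNA can reach. Reads of Serpina1e and Dcpp2 are not easily told from those of their near-identical family members.

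In ciliated epithelium, 3 distal libraries (620, 391 and 959 cells) were compared with proximal 2 and 4 (23 and 30 cells), as proximal 3 had 6 such cells. Crabp1, a retinoic acid binding protein, rose by 6.26 ± 0.65 (log2 fold change ± SE) to 118 ± 21.6 CPM, and Serpina1e by 6.07 ± 0.60 to 598 ± 113 CPM. Efhd1, a mitochondrial calcium binding protein, rose by 4.52 ± 0.73, the heparan sulfate proteoglycan Sdc1 by 4.47 ± 0.64, and the stress cytokine Gdf15 by 4.44 ± 0.70. The small heat shock protein Cryab rose by 4.42 ± 0.76, the interferon-inducible GTPase Irgm1 by 4.32 ± 0.49, and Padi1, an arginine deiminase, by 4.28 ± 0.53. The tight junction gene Cldn10 rose by 4.28 ± 0.80. Several genes had 0 proximal counts. Among them Stoml3, a stomatin family membrane protein, stood at 200 ± 10.3 CPM in distal libraries and was at least 9.68-fold lower in proximal libraries. The lysophospholipase Enpp2 was at least 6.90-fold lower, the urea transporter Slc14a2 at least 6.70-fold and Igfbp2 at least 5.87-fold. For Rgs20 the bound was at least 5.63-fold lower, for the phosphodiesterase Pde10a at least 5.28-fold, for Tent5a at least 5.06-fold and for Dthd1 at least 4.71-fold. These genes had edgeR adjusted p of at most 0.0134 where given with an SE.

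The axonemal list, which holds the dynein motors and arms that drive ciliary beating, had a median log2 fold change of -1.58 over 24 genes in the ciliated class, and 24 of 24 had a value under 0. Of these 2 fell over all genes and 11 adjusted over the list alone. Dnah10 fell from 280 ± 19.1 to 50.1 ± 12.8 CPM (fell by 2.52, SE 0.53) and Dnaic1 from 258 ± 8.25 to 58.1 ± 19.4 CPM (fell by 2.10, SE 0.50). Camera gave adjusted p = 6.7e-14, and adjusted p = 0.248 with an estimated correlation. Camera also placed 7 lists above other genes, none of which passed with an estimated correlation. These were antimicrobial defence (adjusted p = 0.000488, adjusted p = 0.248 with an estimated correlation), interferon response (0.00031 and 0.33), p53 targets (0.00032 and 0.311), stress genes (0.00242 and 0.355), ion transport (0.00242 and 0.248), extracellular matrix (0.0181 and 0.248) and prostaglandins (0.0471 and 0.311).

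Antimicrobial defence (12 genes, median 0.64) had 3 rises over all genes and 4 adjusted over the list alone, the protease inhibitor Wfdc2 (2.83 ± 0.47) among them. Interferon response (18 genes, median 0.89) had 1 rise over all genes, the antiviral membrane protein Bst2 (2.27 ± 0.52), and 4 adjusted over the list alone, Rtp4 (1.99 ± 0.54) among them. The p53 targets (24 genes, median 0.51) had 3 rises over all genes and 5 rises and 1 fall adjusted over the list alone, with Plk2 at 3.39 ± 0.65 and Phlda3 at 2.90 ± 0.42. The stress list (31 genes, median 0.73) had 3 rises over all genes and 5 rises and 4 falls adjusted over the list alone. Its Hspb1 rose by 2.43 ± 0.53 (1839 ± 539 CPM in proximal libraries) and Egr3 by 3.91 ± 0.85. The rise of Egr3 was that of proximal 4 (462 CPM), as proximal 2 stood at 0 CPM and the distal libraries at 5.17 to 32.9 CPM. The fitted -7.64 without proximal 4 rests on this 0 and gives no size or direction. Ion transport (24 genes, median 0.42) had 3 rises over all genes and 5 adjusted over the list alone, with Atp1b1 at 3.73 ± 0.48 and the carbonic anhydrase Car2 at 3.09 ± 0.55. The prostaglandin list (9 genes, median 0.15) had 1 rise by either adjustment, the peptide Edn1 (2.69 ± 0.47). The matrix list (21 genes, median 0.69) and the cell cycle list (9 genes, median 0.56) had 0 calls by either adjustment in edgeR. DESeq2 called 1 gene of each, and 2 and 1 had an unadjusted p under 0.05.

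The Hox list of the ciliated class (18 genes, median -0.51, or -0.19 with genes at 0 counts set to their bound) had 1 rise and 1 fall over all genes and 2 and 2 adjusted over the list alone. Hoxb8 rose by 2.44 ± 0.58 and Nr2f1 was at least 3.96-fold lower. The BMP and TGF-beta list (18 genes, median 0.50, mean -0.30) had 1 rise and 1 fall over all genes and 2 and 1 adjusted over the list alone. Id1 rose by 4.14 ± 0.53 and the coreceptor Tgfbr3 fell by 2.32 on the log2 scale (SE 0.55). The retinoic acid list (11 genes, median -1.74, or -1.21 at the bounds, camera direction up) had 1 rise, Crabp1, and 1 fall over all genes and 2 and 3 adjusted over the list alone. The chemoattractant Rarres2 was at least 4.30-fold lower. The steroid list (15 genes, median -1.03) had 0 rises and 1 fall over all genes and 2 falls adjusted over the list alone. These were the growth factor Areg, with 1422 distal and 2 proximal counts (ratio 0.0553, 0.00669 to 0.200), and Pgrmc1 (fell by 1.77, SE 0.55). Wnt (22 genes, median 0.12, mean -0.39) had 1 rise by either adjustment, Wnt5a (3.06 ± 0.56). Notch (13 genes, median -0.06, camera direction up) had 1 rise as well, the transcription factor Hes1 (1.48 ± 0.37). The ovarian carcinoma list (42 genes, median -0.59, or -0.38 at the bounds, camera direction up) had 2 rises and 1 fall over all genes and 3 and 3 adjusted over the list alone. Ccnd2 rose by 2.77 ± 0.50, and the checkpoint kinase Chek2 had a ratio of 0.0552 (0.0014 to 0.309).

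A total of 334 of 11617 genes passed in ciliated epithelium, 180 up and 154 down with TMM scaling (edgeR, with 2278 at an unadjusted p under 0.05 and 838 by DESeq2). With RLE size factors the split was 209 up and 118 down, and the median of all genes moved from -0.32 to -0.19 on the log2 scale. With a term for distal 2 and proximal 2, 550 genes passed, 300 up and 250 down, and with the description number as a block 65, 51 up and 14 down. Within these libraries alone the fold was 0.01 for Efhd1, 0.09 for Gdf15, 1.28 for Plk2 and -2.02 for Egr3, which stood at 0 CPM in proximal 2. Plk2 stood at 29.6 CPM in proximal 2, inside the distal range of 11.2 to 32.9 CPM, and at 400.5 CPM in proximal 4. The rise of Cldn10 was mostly that of proximal 2 (355 CPM, against 20.5 CPM in proximal 4), with a fold of 5.90 in this pair and 0.98 in the other libraries. In proximal 4, 28 of the 30 cells lay in cluster E7. At resolution 2 only 4 of the 30, and 0 of the 6 cells of proximal 3, stayed in a ciliated-like cluster. There, cluster 19, classed as non-ciliated and led by Efhd1, Krt17 and Gdf15 among others, held 28 cells of proximal 4. In proximal 4, 76.7% of its cells had at least 3 ciliated markers against 99.0% of the cells of distal 1 thinned in depth. Calls numbered 190 without distal 1, 137 without distal 2, 41 without distal 3, 1018 without proximal 2 and 809 without proximal 4. The lone proximal library of the last pair was assumed to vary like the others. They numbered 74 with distal sums thinned.

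In fibroblasts the largest rises among the named genes included Hoxa9 and Hoxa10, of the Hox genes that pattern the female reproductive tract along its axis. Hoxa9 rose by 5.78 ± 0.30 (log2 fold change ± SE, 3 libraries against 3), from 1.45 ± 0.4 to 80.5 ± 2.56 CPM. Hoxa10 had 1 distal and 35 proximal counts, a pooled ratio of 272 (95% counting interval 45.7 to 11036). Other proximal rises were those of the syntrophin Sntg1 (3.68 ± 0.65), the sarcoglycan Sgcz (3.61 ± 0.68), the fibronectin domain protein Fndc1 (3.39 ± 0.47) and Zfp804b (3.07 ± 0.35). Rises followed in the copine Cpne5 (3.06 ± 0.45), the hedgehog receptor Ptch1 (3.06 ± 0.54, to 167 ± 119 CPM) and the protease Adamts19 (2.82 ± 0.41). The activin antagonist Fst fell by 3.52 on the log2 scale (SE 0.41), from 33.7 ± 3.65 to 4.63 ± 3.53 CPM. The secreted Wnt modulator Sfrp2 fell by 2.94 (SE 0.45), from 140 ± 44.1 to 14.2 ± 13.7 CPM. The synaptic adhesion gene Nrxn3 fell by 3.03 (SE 0.62), the mitochondrial gene Chchd10 by 3.02 (SE 0.35, from 221 ± 50 to 27.5 ± 6.75 CPM), Rgs16 by 2.99 (SE 0.54) and Pde4b by 2.95 (SE 0.69). Gimap6, Dcpp3 and Plvap, which fell by 4.19, 4.06 and 3.93 (SE 0.58, 0.80 and 0.55), stood at 1.09%, 0.78% and 2.53% of their level in T or NK, non-ciliated epithelial and blood endothelial cells, a level that free RNA can reach. The genes given with an SE here had edgeR adjusted p between 1.1e-05 and 0.048.

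The Hox list of fibroblasts (26 genes, median -0.03, mean 0.72) had 4 rises over all genes, and 4 rises and 1 fall adjusted over the list alone. Camera gave direction up with adjusted p = 0.0111, and adjusted p = 0.918 with an estimated correlation. The stress list (31 genes, median -0.55) had 1 rise and 1 fall over all genes and 1 and 2 adjusted over the list alone. Hspa1b rose by 1.89 ± 0.38 and the transcription factor Klf2 fell by 1.35 on the log2 scale (SE 0.30), from 865 ± 116 to 344 ± 44 CPM. Camera gave it direction down with adjusted p = 0.00249, and adjusted p = 0.913 with an estimated correlation. No other list passed camera in fibroblasts. The BMP and TGF-beta list (31 genes, median -0.11) had 4 falls over all genes, Fst and Gdf10 (fell by 1.92, SE 0.36) among them, and 2 rises and 5 falls adjusted over the list alone. Ion transport (15 genes, median 0.04) had 2 rises over all genes, the sodium channel subunit Scnn1b (2.28 ± 0.45) and the carbonic anhydrase Car12 (1.67 ± 0.34), and 4 rises and 2 falls adjusted over the list alone. Antimicrobial defence (17 genes, median -0.06) had 2 rises and 1 fall over all genes and 3 and 5 adjusted over the list alone. Complement C3 rose from 90.4 to 341 ± 26.5 CPM (1.91 ± 0.34), and the trefoil peptide Tff3, at 0 distal and 23 proximal counts, was at least 59.5-fold higher.

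The matrix list of fibroblasts (43 genes, median 0.10) had 2 rises and 1 fall by either adjustment, with the elastic fibre gene Fbln5 rising from 38.7 ± 5.02 to 87.7 ± 31.0 CPM and the glycoprotein Tnc falling by 2.66 on the log2 scale (SE 0.53). The Wnt list (36 genes, median 0.04) had 1 rise, Wnt5b (2.25 ± 0.50), and 1 fall, Sfrp2, over all genes and 2 and 3 adjusted over the list alone. The prostaglandin list (18 genes, median -0.42) had 1 rise, the degrading enzyme Hpgd (2.06 ± 0.31), and 1 fall, the cyclooxygenase Ptgs1 (fell by 2.33, SE 0.52), over all genes and 2 and 3 adjusted over the list alone. Notch (14 genes, median 0.02, mean -0.11) had 1 fall by either adjustment, Heyl (fell by 1.74, SE 0.40). A further 3 lists had 0 calls over all genes in edgeR and falls adjusted over the list alone (retinoic acid, cell cycle and p53 targets, with 5, 5 and 7 genes at an unadjusted p under 0.05 and 0, 0 and 3 called by DESeq2). Retinoic acid (14 genes, median 0.23) had 1 such fall, in the retinol transporter gene Stra6 (fell by 2.18, SE 0.57). Cell cycle (24 genes, median -0.39) had 1, in the centromere gene Cenpa (fell by 2.02, SE 0.49). The p53 targets (24 genes, median -0.31) had 2, in Btg2 (fell by 1.45, SE 0.38) and Gadd45a (fell by 1.36, SE 0.34). Steroid hormone (15 genes, median -0.19), ovarian carcinoma (44 genes, median -0.06), axonemal (11 genes, median -0.28) and interferon genes (25 genes, median -0.32) had 0 calls by either adjustment in edgeR and 0 by DESeq2, with 1, 6, 0 and 4 genes at an unadjusted p under 0.05.

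**Figure D3:**
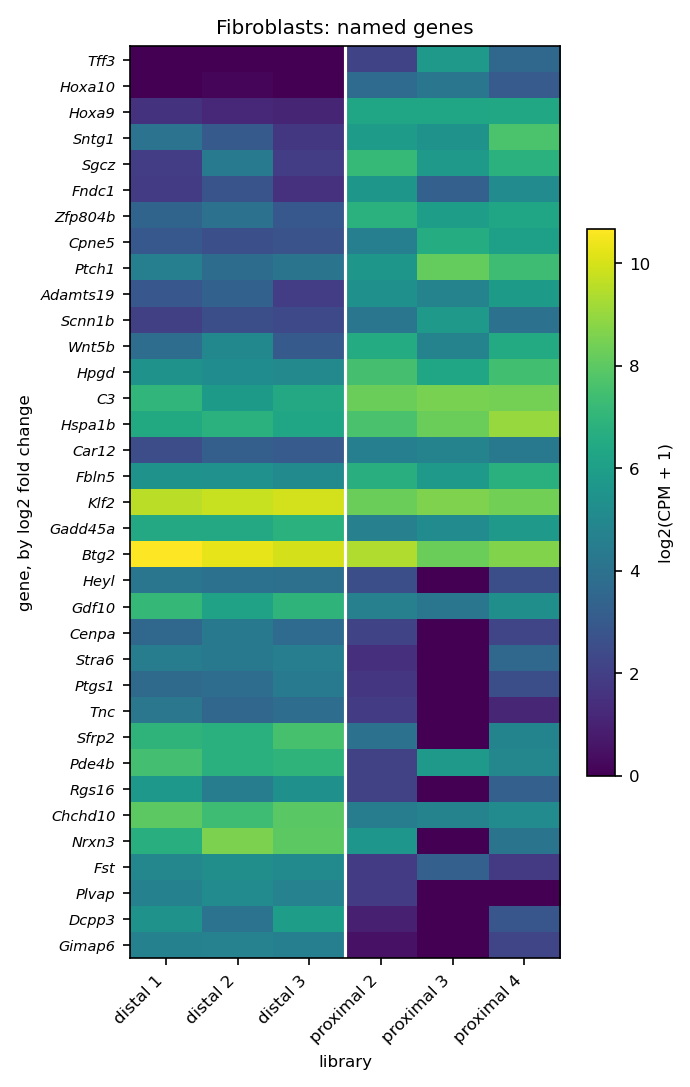
Heatmap of log2 of CPM plus 1 for the named genes of fibroblasts (vertical axis) in each of the 6 libraries (horizontal axis). Hoxa9 averaged 1.45 CPM in the distal and 80.5 CPM in the proximal libraries.

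The fibroblast comparison called 391 of 13709 genes, 269 up and 122 down (edgeR quasi-likelihood test, 2312, 2384 and 2252 distal and 375, 132 and 610 proximal cells). An unadjusted p under 0.05 was reached by 2233 genes and DESeq2 called 517. With a term for distal 2 and proximal 2, 1183 genes passed, 653 up and 530 down, and between these libraries alone the folds were 5.56 for Hoxa9, -3.59 for Fst and 0.79 for Hspa1b. Wnt5b stood at 26.1 CPM in proximal 3, below the 30.5 CPM of distal 2. Different clusters held the fibroblasts of each library. Cluster 13, with Sgcz and Cpne5 among its leading genes, held 65 and 179 cells of proximal 3 and 4 and 19, 8 and 3 distal cells. Cluster 11, with Zfp804b among its own, held 206 cells of proximal 2 and 321 of distal 2, and cluster 10, led by Nrxn3 among others, held 673 cells of distal 2. Within 1 cluster with cells of all 6 libraries 168 genes passed. Calls numbered 41 without distal 1, 178 without distal 2, 95 without distal 3, 1939 without proximal 2 and 75 without proximal 3, and 155 with distal sums thinned.

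In the smooth muscle class, 3 distal libraries (1263, 152 and 421 cells) were compared with proximal 3 and 4 (29 and 46 cells). Cells of the regions lay mostly in different clusters, as given below. The alpha-1A adrenergic receptor Adra1a rose by 4.92 ± 0.46 (log2 fold change ± SE), from 9.59 to 356 ± 28.4 CPM, and the sphingosine phosphate receptor S1pr3 by 4.73 ± 0.39, from 15.6 to 502 ± 56.3 CPM. The glutamate receptor scaffold Grip2 (4.84 ± 0.49), the transcription factors Meox2 (4.75 ± 0.59) and Foxc1 (4.50 ± 0.57), and the cationic amino acid transporter Slc7a2 (4.50 ± 0.52) rose. So did the TGF-beta docking receptor Lrrc32 (4.38 ± 0.53) and the diacylglycerol kinase Dgkg (4.29 ± 0.46). Genes with 0 proximal counts were the collagen Col12a1, at least 10.0-fold lower, Ifitm1, at least 7.89-fold, Dock4, at least 5.08-fold, and the prepronociceptin gene Pnoc, at least 4.76-fold. Others were the mitochondrial membrane protein Tspo, at least 4.23-fold, the potassium channel Kcnj8, at least 3.77-fold, Manf, at least 3.55-fold, and Snrpd1, at least 3.46-fold. The genes given with an SE here had edgeR adjusted p of at most 8.2e-13.

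The stress list of smooth muscle (30 genes, median 0.44) had 6 rises and 2 falls over all genes and 7 and 2 adjusted over the list alone. The immediate early receptors Nr4a1 (2.07 ± 0.34) and Nr4a2 (1.69 ± 0.34) were among the rises. Camera gave it adjusted p = 0.0015, and adjusted p = 0.715 with an estimated correlation. The ovarian carcinoma list (36 genes, median 0.38) had 3 rises and 2 falls by either adjustment, with the cell cycle inhibitor Cdkn1a at 2.47 ± 0.34 and the survival gene Bcl2 falling by 2.12 on the log2 scale (SE 0.61). Camera gave it adjusted p = 0.0399, and adjusted p = 0.715 with an estimated correlation. The Hox list (18 genes, median -0.66) had 6 falls by either adjustment. Meis2, a cofactor of Hox proteins, fell from 641 ± 28.4 to 79.7 ± 6.22 CPM (fell by 3.04, SE 0.56), and Hoxa5 had a ratio of 0.115 (0.0237 to 0.336). The steroid list (15 genes, median -0.42) had 2 falls by either adjustment, the oestrogen receptor Esr1, from 1408 ± 160 to 537 ± 13.8 CPM (fell by 1.40, SE 0.41), and Pgr (fell by 1.72, SE 0.51). In Notch (9 genes, median 0.06, mean -1.06, camera direction up) 3 genes rose by either adjustment, Heyl (4.24 ± 0.67) and Hes1 (1.85 ± 0.34) among them.

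The Wnt list of smooth muscle (26 genes, median -1.26, or -0.22 with genes at 0 counts set to their bound) had 1 rise and 3 falls over all genes and 1 and 5 adjusted over the list alone. Sfrp2 was at least 2.73-fold lower, and the R-spondin Rspo3 had a ratio of 0.0757 (0.00917 to 0.274). The matrix list (37 genes, median -0.27, or 0.00 at the bounds, camera direction up) had 7 rises and 5 falls over all genes and 8 and 7 adjusted over the list alone. Thrombospondin, Thbs1, rose from 96.5 to 1506 ± 703 CPM (3.99 ± 0.33). BMP and TGF-beta (26 genes, median 0.02, mean -1.24, camera direction up) had 3 rises and 3 falls over all genes and 4 and 3 adjusted over the list alone. Tgfb3 rose by 2.08 ± 0.47 and Tgfbr3 fell by 1.98 (SE 0.46). Retinoic acid (9 genes, median -0.02) had 2 falls by either adjustment, Rarres2 (fell by 2.04, SE 0.47) among them. Ion transport (11 genes, median -0.24, or 0.00 at the bounds) was the only list to pass fry, which asks whether its genes moved one way on balance (direction down, adjusted p = 0.00344). It did not pass camera (adjusted p = 0.585, and adjusted p = 0.715 with an estimated correlation). It had 2 falls by either adjustment, the water channel Aqp1 (ratio 0.0865, 0.0105 to 0.313) among them. Antimicrobial defence (11 genes, median -1.33, or -0.98 at the bounds) had 2 falls by either adjustment, Wfdc18, at least 2.12-fold lower, and Wfdc1 (ratio 0.193, 0.0233 to 0.698). Prostaglandins (8 genes, median -0.36, or 0.18 at the bounds, camera direction up) had 1 rise by either adjustment, the endothelin receptor Ednrb (3.51 ± 0.62). The p53 targets (19 genes, median -0.55, or -0.53 at the bounds, camera direction up) had 2 rises, Gadd45b (2.92 ± 0.33) and Gadd45g (1.45 ± 0.34), and 1 fall by either adjustment. Interferon response (9 genes, median -0.11, or 0.00 at the bounds) had 1 rise, Irf9 (2.11 ± 0.70), and 1 fall, Ifitm3 (fell by 2.36, SE 0.44), by either adjustment. Cell cycle (7 genes, median -0.39, camera direction up) had 0 calls by either adjustment in edgeR, 0 by DESeq2 and 0 genes at an unadjusted p under 0.05, and fewer than 5 axonemal genes could be tested.

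In smooth muscle 1204 of 9487 genes passed, 450 up and 754 down (edgeR, 3 libraries against 2, with 2531 at an unadjusted p under 0.05 and 983 by DESeq2). The group 2 libraries gave no value of their own here, because proximal 2 had no smooth muscle cells. Most distal cells lay in cluster 5, led by Actg2 and Cnn1 (1129, 148 and 395 cells), and most proximal cells in cluster 16 (26 and 38 cells), led by Pln and S1pr3 among others. Within cluster 16 alone 104 genes passed and Esr1 turned to 0.24. At resolution 0.5 the mean proximal smooth muscle share was 0.543%, against 4.33% at resolution 1, so most of these proximal cells left the class. The calls thus compare largely different clusters, and a region difference within 1 kind of muscle cell cannot be told apart from this. Calls numbered 452 without proximal 3 and 212 without proximal 4, the other proximal library being assumed to vary like the distal ones. They numbered 409 with distal sums thinned.

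Marker and tumour genes were compared between epithelial classes of the 3 distal libraries. Ovgp1, the oviductal glycoprotein secreted into the lumen, stood at 27066 ± 4276 CPM in cluster E1, 10564 ± 997 in E8, 6983 ± 2118 in E10 and 2286 ± 628 in the ciliated class. Pax8, a transcription factor of the Müllerian epithelium, stood at 243 ± 46.1 CPM in non-ciliated epithelium as a whole, 169 ± 18.8 in E10, 165 ± 38.6 in E8, 111 ± 8.86 in E1 and 64.9 ± 20.8 in the ciliated class, against 1.93 ± 0.293 in fibroblasts. The glutamate transporter Slc1a3 stood at 489 ± 109 CPM in non-ciliated epithelium, 280.2 ± 28.8 in E8, 262 ± 54.6 in E10, 152 ± 52.2 in E1 and 17.1 ± 9.24 in the ciliated class. Sox9, a transcription factor of progenitor cells in several epithelia, ran from 76.6 ± 20.1 CPM in the ciliated class to 167 ± 39.9 in non-ciliated epithelium. Foxj1, the regulator of motile cilia, reached 964 ± 80.4 CPM in the ciliated class and 541 ± 175 in E10, against 23.3 ± 17.9 in E8 and 15.7 ± 5.62 in E1. Trp73, a p53 family gene needed for multiciliated cells, reached 121 ± 11.2 CPM in the ciliated class and 59.4 ± 17.3 in E10, against 1.81 ± 1.15 in E1. Prom1, which encodes a membrane protein of protrusions, stood at 270 ± 105 CPM in the ciliated class, 178 ± 69.8 in E8 and 58.8 ± 16.9 in E1. Krt5, a basal keratin, stood at 2.18 ± 0.522 CPM in the ciliated class and was listed at 0 in E1 and E8. The tumour suppressor Rb1 stood at 77.2 ± 7.44 CPM in the ciliated class, 49.2 ± 6.15 in E10 and 10.1 ± 5.09 in E1. Trp53 stood in the opposite order, at 8.27 ± 1.79, 22.7 ± 2.13 and 41.6 ± 4.58 CPM. All but Rb1 and Trp53 were among the markers used to name clusters.

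**Figure D4:**
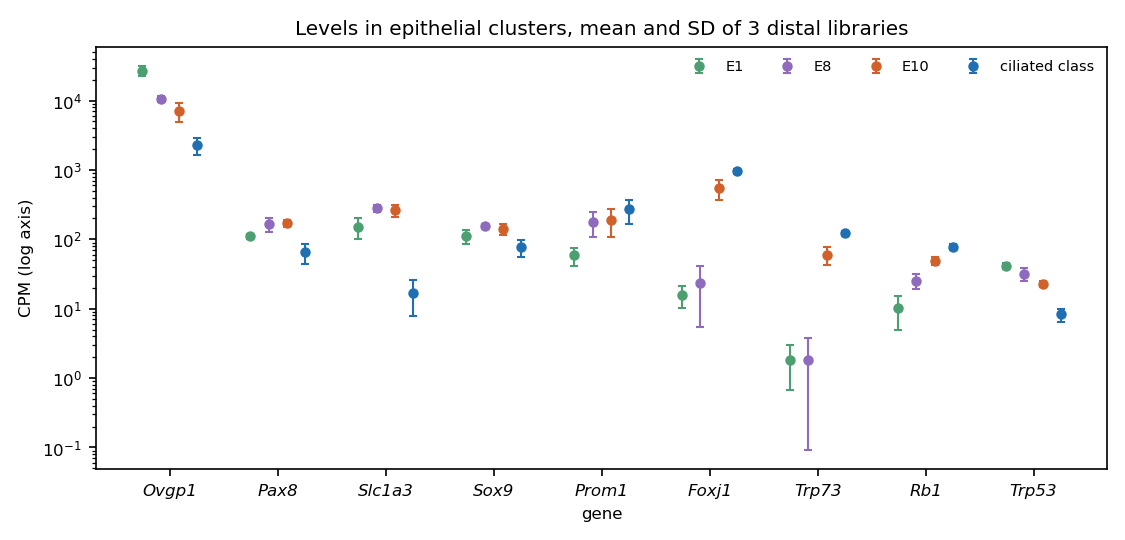
Level in CPM on a log axis (vertical) of 9 marker and tumour genes in clusters E1, E8 and E10 and in the ciliated class, as the mean and SD of the 3 distal libraries. Ovgp1 stood at 27066 CPM in E1 and 2286 CPM in the ciliated class, and Foxj1 at 15.7 and 964 CPM.

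No epithelial cluster met the naming rule for pre-ciliated or secretory cells, so the comparisons are given by cluster. E10 had the highest pre-ciliated score outside the ciliated class (0.62), below those of the ciliated clusters E7, E4 and E2 (0.97, 0.93 and 0.78). Cluster E1 had the highest secretory score, and E8 met the rule for progenitor. Cells of E10 had a median of 16267.5 UMIs and cells of E1 2868.5. The smooth muscle genes Myh11 and Tagln were among the leading genes of E10, and its median doublet scores were 0.714, 0.838 and 0.781 against 0.341, 0.495 and 0.342 in other cells of the distal libraries. Against E1, cluster E10 had higher axonemal genes, 24 of 24 by either adjustment with a median log2 difference of 6.30, with Dnah12 at 8.40 ± 0.42 (517 ± 163 CPM in E10) and Dnah5 at 7.35 ± 0.37 (508 ± 72 CPM). Stress and immediate early genes followed, with 25 of 30 higher and 2 lower (median 2.74), Klf6 at 5.62 ± 0.33 and Fosb at 4.71 ± 0.29. In the matrix list 14 of 19 were higher and 1 lower (median 2.31), with the protease Adamts1 at 4.15 ± 0.51 higher and the fibulin Fbln2 lower (-2.82 ± 0.31). In the ovarian carcinoma list 29 of 39 were higher and 2 lower (median 1.74), with the transcription factor Mecom at 3.94 ± 0.29 and Mcl1 at 3.02 ± 0.26. BMP and TGF-beta genes were higher for 12 of 21 and lower for 2 (median 1.71), with Tgfbr3 at 4.40 ± 0.39 and Bmpr1b at 2.90 ± 0.29. Wnt genes were higher for 12 of 20 and lower for 1 (median 1.25), with Ctnnb1 at 1.52 ± 0.24. Antimicrobial genes were lower for 7 of 11 and higher for 0 (median -0.81), the mucin-folding enzyme Agr2 at -3.01 ± 0.36 and Wfdc2 at -1.61 ± 0.26 among them.

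Other lists of E10 against E1 moved both ways by either adjustment. Steroid genes were higher for 8 of 14 and lower for 3 (median 1.15, Ncoa2 at 4.04 ± 0.32). The p53 targets were higher for 10 of 21 and lower for 6 (median 0.91, Gadd45b at 2.99 ± 0.32 and Btg2 at 2.81 ± 0.28). Retinoic acid genes were higher for 6 of 10 and lower for 1 (median 0.98, Rarres2 at 2.47 ± 0.37, and the degrading enzyme Cyp26a1 lower at -3.17 ± 0.40). Ion transport genes were higher for 11 of 19 and lower for 4 (median 0.82, Fxyd4 at 3.40 ± 0.37 and Fxyd3 at -2.66 ± 0.31). Hox genes were higher for 7 of 18 and lower for 5 (median 0.44, Hoxb6 at -2.12 ± 0.26). Prostaglandin genes were higher for 5 of 10 and lower for 2 (median 0.39, Slco2a1 at 1.25 ± 0.26 and Ptgds at -1.45 ± 0.41). Notch genes were higher for 5 of 14 and lower for 3 (median -0.14, Numb at 3.64 ± 0.38). Interferon genes were higher for 4 of 15 and lower for 3 (median -0.34, Cxcl10 at 3.66 ± 0.54). Cell cycle genes were higher for 1 of 6 and lower for 1 (median -0.38, Mcm4 at 1.20 ± 0.53 and Tyms at -1.92 ± 0.41). In total 215 of 290 fixed-list genes passed, 172 higher and 43 lower (edgeR with the library as a block, 3 distal libraries, adjusted over the list alone and equally many over all genes). These genes differed in the same direction in 3 of 3 libraries. Of all 10552 genes tested 6792 passed, 3740 higher and 3052 lower, with a median of 0.12.

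Against the ciliated class, all 24 axonemal genes were lower in E10 by either adjustment (median -1.08), with Dnali1 at -1.56 ± 0.24 (197 ± 58.2 against 559 ± 64.6 CPM) and Dnaaf1 at -1.57 ± 0.26. Antimicrobial genes were higher for 10 of 12 (median 2.26), the iron-binding Ltf (3.61 ± 0.31) and the mucin Muc1 (3.41 ± 0.29) among them, and 1 was lower adjusted over the list alone but 0 over all genes. Matrix genes were higher for 16 of 26 adjusted over the list alone and 15 over all genes (median 1.54), with fibronectin, Fn1, at 3.70 ± 0.28 and Sparc at 3.17 ± 0.27. BMP and TGF-beta genes were higher for 12 of 19 (median 1.06, Ltbp1 at 2.66 ± 0.26) and lower for 1 adjusted over the list alone and 0 over all genes. Ion transport genes were higher for 12 of 24 and lower for 5 adjusted over the list alone and 3 over all genes (median 0.66), with the chloride channel Ano1 at 3.67 ± 0.28. Stress genes were higher for 16 of 31 and lower for 7 adjusted over the list alone, 15 and 6 over all genes (median 0.62), with Ier3 at 2.47 ± 0.24 and Egr1 at 1.96 ± 0.23. Interferon genes were higher for 7 of 17 and lower for 2 (median 0.49, Isg15 at 2.52 ± 0.38). Wnt genes were higher for 9 of 24 and lower for 1 (median 0.20, Wnt5b at 2.84 ± 0.32 and Dkk3 at 2.44 ± 0.24).

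Prostaglandin genes of E10 against the ciliated class were higher for 5 of 11 and lower for 2 adjusted over the list alone, 5 and 1 over all genes (median 0.46, the transporter Slco2a1 at 2.85 ± 0.28). Steroid genes were higher for 5 of 16 and lower for 2, 4 and 2 over all genes (median 0.25, Zbtb16 at 2.51 ± 0.44). The p53 targets were higher for 9 of 23 and lower for 3, 7 and 3 over all genes (median 0.14, Plk2 at 1.88 ± 0.28). Retinoic acid genes were higher for 2 of 11, Rdh10 at 0.81 ± 0.29 among them, and lower for 2, or 0 over all genes (median -0.05). Notch genes were higher for 4 of 13 and lower for 2 (median -0.10, Notch1 at 1.45 ± 0.27). Hox genes were higher for 2 of 18 and lower for 0 (median 0.18, Hoxb6 at 0.70 ± 0.23). Ovarian carcinoma genes were higher for 8 of 42 and lower for 5, 8 and 2 over all genes (median -0.08, Ccnd1 at 3.08 ± 0.46 and Bcl2 at 3.07 ± 0.32). Of 9 cell cycle genes 1 was lower, Hmgb2 at -0.92 ± 0.34 in 2 of 3 libraries (median -0.21). In total 175 of 319 fixed-list genes passed adjusted over the list alone, 117 higher and 58 lower, and 159 over all genes (edgeR, library as a block). Of all 12101 genes tested 3805 passed, 2054 higher and 1751 lower (median 0.02). Cells of E10 had median depths of 11781, 20733 and 15717 UMIs in the 3 distal libraries, against 2805, 2177 and 1759 in the ciliated class and 4091, 4442 and 6553 in non-ciliated epithelium.

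Cells of E8 had a median of 9404 UMIs and cells of E1 2868.5, and the haemoglobin gene Hbb-bs was among the leading genes of E1. Cluster E8 against E1 showed its largest differences in stress and immediate early genes, 23 of 30 higher and 1 lower (median 2.45), with Klf6 at 6.30 ± 0.19 (1872 ± 322 CPM in E8) and Egr1 at 4.95 ± 0.17 (1239 ± 374 CPM). BMP and TGF-beta genes were higher for 13 of 19 and lower for 1 (median 1.39, Ltbp1 at 4.10 ± 0.28 and Bmpr1b at 3.12 ± 0.22). Ovarian carcinoma genes were higher for 29 of 39 and lower for 2 (median 1.27, Mecom at 4.10 ± 0.19). Steroid genes were higher for 9 of 14 and lower for 4 (median 1.27), with Esr1 at 1.76 ± 0.17 (694 ± 49 against 220 ± 104 CPM) and Ncoa2 at 3.58 ± 0.28. Ion transport genes were higher for 12 of 19 and lower for 5 (median 1.03, the cotransporter Slc12a2 at 1.75 ± 0.18 and Car2 at -2.40 ± 0.24). Wnt genes were higher for 11 of 18 and lower for 2 (median 0.86, Znrf3 at 2.54 ± 0.30 and Tcf7l2 at 2.13 ± 0.22). Hox genes were higher for 10 of 19 and lower for 6 (median 0.70, Meis2 at 1.52 ± 0.16). Retinoic acid genes were higher for 3 of 8 and lower for 1 (median 0.64, Dhrs9 at 3.10 ± 0.27 and Cyp26a1 at -4.60 ± 0.37). Notch genes were higher for 4 of 12 and lower for 2 (median 0.35, Numb at 3.45 ± 0.33). Matrix genes were higher for 6 of 14 and lower for 2 (median 0.33, Adamts1 at 4.79 ± 0.38 and Fbln2 at -2.19 ± 0.22). Antimicrobial genes were higher for 5 of 12 and lower for 3 (median 0.25, Wfdc2 at -1.78 ± 0.17 and Agr2 at -1.29 ± 0.13). The p53 targets were higher for 8 of 22 and lower for 6 (median 0.10, Btg2 at 3.18 ± 0.14). Prostaglandin genes were higher for 4 of 13 and lower for 2 (median -0.02, Slco2a1 at 2.40 ± 0.18). Interferon genes were higher for 4 of 13 and lower for 6 (median -0.50, Cxcl10 at 5.27 ± 0.36 and Rtp4 at -2.02 ± 0.28). Of 7 cell cycle genes 1 was lower, Tyms at -1.04 ± 0.30 (median -0.44). Fewer than 5 axonemal genes could be tested, of which Dnaaf5 was higher at 1.25 ± 0.47. In total 186 of 260 fixed-list genes passed by either adjustment, 142 higher and 44 lower (edgeR, library as a block). Among all 10210 genes tested 3239 were higher and 2975 lower, 6214 in total (median -0.006).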

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

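The tests of the group 2 libraries and of other splits of the libraries were chosen after the results were seen, and the single-cluster and thinned comparisons were alternatives added after seeing the data. The interaction test between cell classes is given for all genes it called in total and for single genes chosen after their values were seen.

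The region difference of 288 of 15809 genes differed between non-ciliated epithelium and fibroblasts in an edgeR test of the difference itself, with the library as a block. For 141 of these the proximal effect was larger in epithelium. Cyclin D2, Ccnd2, differed by 5.85 on the log2 scale (4.92 in epithelium against -0.85 in fibroblasts), the metallothionein Mt2 by 5.71 (4.64 against -1.02), and Penk, the enkephalin precursor, by 7.07 (6.63 against -0.45). The Id genes, targets of BMP signalling in many cells, moved apart, by 5.20 for Id1 (3.21 against -1.85), 3.68 for Id2 (2.18 against -1.36) and 3.55 for Id3 (1.98 against -1.48). Tinagl1, a matrix glycoprotein, differed by 4.55 (2.47 against -2.24), and the interferon-inducible GTPase Iigp1 by 4.10 (2.69 against -1.67). Thsd4, a thrombospondin domain protein, differed the other way by -6.07 (-3.57 against 2.60). Of these genes Id2, Id3, Tinagl1, Iigp1 and Thsd4 were called in both classes in opposite directions, 5 genes in all. Penk is a leading gene of the proximal epithelial cluster E11, and Id1 and Id2 of the proximal cluster E13.

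Haemoglobin took 97.3% of the UMIs of the barcodes that the cell filter removed from proximal 2, and 59.4%, 86.3% and 67.5% in the distal libraries, 34.2% in proximal 4 and 0% in the only barcode removed from proximal 3. In the kept cells of the 6 libraries it took at most 0.415%. The red cell barcodes enter no comparison. A cluster with granulosa or luteal markers, steroid-producing cells of the ovary, held 62 distal cells (30, 18 and 14 per library), whereas 0 of 2282 proximal cells lay in it, which allows a share of up to 0.131%.

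Cluster E10 carried ciliated genes together with genes of non-ciliated epithelium, its leading genes also included the smooth muscle genes Myh11 and Tagln, and its size differed between libraries. Of 13 detected multiciliogenesis markers 1, E2f7, was highest in E10, whereas Ccno and Deup1 were highest in E2. This went against the prediction set for passage toward multiciliogenesis, but it cannot exclude such passage. Some markers were also high in ciliated clusters (Trp73 at 156 CPM in E4 and 64.1 in E10). Others were near the floor in every cluster (Mcidas at most 1.72 CPM). Doublets of a ciliated and a non-ciliated cell may account for it, since 0 genes lay above 2 times every other cluster in each distal library, against 40, 63, 39 and 28 genes in the ciliated clusters E2, E4, E7 and E12, although clusters E1, E3, E5 and E6 also had 0. The median doublet score of E10 was 0.714, 0.838 and 0.781 in the distal libraries against 0.341, 0.495 and 0.342 in other cells. Its median depth was 11781, 20733 and 15717 UMIs. The ciliated class had 2805, 2177 and 1759, and non-ciliated epithelium 4091, 4442 and 6553. A pair of such median cells would fall short of the depth of E10, but depth differed between the clusters of each class. Cluster medians over all libraries ran from 1903.5 (E13) to 10594 UMIs (E3) in non-ciliated epithelium. They ran from 1091 (E2) to 4465 (E7) in the ciliated class. Depth therefore does not decide for or against these doublets. Doublet removal took E10 from 96 to 15 cells in distal 1, 48 to 31 in distal 2 and 259 to 196 in distal 3, where 20, 6.6 and 22 such doublets were expected, so the numbers before removal exceed the assumed rate and a true intermediate state stays open.

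Axonemal genes were lower in the ciliated class of proximal libraries, with a median of -1.58. Without proximal 4 the median was -2.39 (interquartile range 1.36), against -0.98 for all genes, and without proximal 2 it was -1.25, against -0.47 for all genes (-0.32 with all libraries). The fall without proximal 4 runs against other cells there as the whole cause, but it rests on 23 cells of proximal 2 alone and lies below that of all genes by 1.41, little over its spread, so this is not settled. Lower depth stays open too, because thinning the distal sums leaves the expected ratios as they were, and the median of -1.15 over 19 genes decides nothing. A region difference in ciliated cells and free RNA are also open, with ciliated markers at 4787 CPM in proximal 4, 11060.3 in proximal 2 and 14059 in distal 1, and Krt8 at 1711, 707 and 401 CPM.

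For the genes called in non-ciliated epithelium, leaving out both group 2 libraries (385 of the 400 called again) does not test a batch of theirs, since they hold 1 library of each region. A shift common to both would weigh alike on the regions, so by the design it could not by itself make these calls. With a term for it 400 of the 400 were called again in the same direction, with a median fold of 2.82 against 2.89. Other sub-clusters in each region stay open, since within cluster 4 the median fold in the called direction was 1.56 (interquartile range 1.38) against 2.51 over all cells for the same 122 genes, 112 with the same direction, in 3 libraries against 2 that rest largely on proximal 2 (174 cells, with 24 of proximal 4 and 4 of proximal 3, too few to enter). Lower depth stays open, because thinning leaves the expected ratios as they were, so that medians of 2.76 after and 2.75 before (202 genes, 110 called again) decide nothing. The split of the 6 libraries could not be weighed against others, since 10 splits are too few for a share under 0.05, and the real split gave 400 calls here and 391 in fibroblasts where the highest other gave 0 in edgeR, so 1 split of 10 was as large. The cluster comparisons allow 4 splits, also too few, with 215, 175 and 186 genes for the real ones and 0 for the highest other in edgeR, so 1 split of 4 was as large.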

How the results depend on the processing

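The single-cluster, thinned and group 2 settings were chosen after seeing the data. Of 123 alternative counts of calls, 82 lay within 1.5 times the count given, 26 below and 15 above. Of 65 alternative shares 4 reversed and 2 passed, but the exact tests could not pass in any setting. Depth limits the proximal side, where smooth muscle rests on 29 and 46 cells and the ciliated class on 23 and 30.

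Calls in non-ciliated epithelium numbered 400, and 1491 with DESeq2, 1352 without the low-count filter, 249 at resolution 2, 44 within a single cluster, 111 with thinned sums, 3507 with both group 2 libraries left out and 1507 with a term for group 2. Ciliated calls numbered 334, and 838 with DESeq2, 860 without the filter, 74 with thinned sums, 1386 without group 2 and 550 with the group 2 term. Fibroblast calls numbered 391, and 1378 without the filter, 168 within a single cluster, 155 thinned, 2176 without group 2 and 1183 with the group 2 term. Smooth muscle calls numbered 1204, and 104 within a single cluster and 409 thinned. Fewer cells or counts lower the count by construction in the single-cluster and thinned settings, and for the others the cause was not tested. Leaving out 1 library gave 6 to 3204 calls in non-ciliated epithelium, 41 to 1018 in the ciliated class, 41 to 1939 in fibroblasts and 212 to 1144 in smooth muscle, where a lone proximal library was assumed to vary like the others. Between clusters it gave 196 to 222, 129 to 180 and 143 to 196 genes.

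With a replicate block, which pairs sections by number, calls were 551 (title) and 532 (description) in non-ciliated epithelium, 506 and 524 in fibroblasts, and 65 (description) in the ciliated class. All block fits rest on the numbers found in both regions, 2 and 3 by title and 2 and 4 by description. They leave little from which to estimate the spread. In edgeR on cell numbers with the title block, the ciliated share fell by 2.22 on the log2 scale (adjusted p = 0.0158) and the fibroblast share reversed to -0.19. The E10 share was fitted at -8.40 (adjusted p = 0.029), and at -3.36 without the block (adjusted p = 0.208). Proximal 2 and 3 had 0 E10 cells, which allows up to 1.01% and 3.16%, against 2.48% and 8.42% in distal 2 and 3. The fitted fold therefore has no exact size. Both numbers pair distal 2 with proximal 2, whose residuals correlated across genes at 0.746 in non-ciliated epithelium and 0.581 in fibroblasts. Distal 3 correlated at 0.536 and 0.242 with proximal 3 (title) and at 0.609 and 0.066 with proximal 4 (description), so its pair was not settled. Without the library block the cluster comparisons gave 215, 150 and 172 genes.

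The fibroblast share also reversed with at least 500 genes per cell (-1.24 points), without distal 1 (-3.10) and without proximal 4 (-1.69), and the cause was not tested. Leaving out 1 library gave -13.5 to -3.36 points for the epithelial share, -26.1 to -18.8 for the ciliated share, -5.07 to -1.19 for E10, -3.10 to 8.49 for fibroblasts and -9.05 to -1.41 for smooth muscle. Of 63 list tests 14 passed with camera, 0 with an estimated correlation and 1 with fry, and 3 of 32 with the title block. Among named region genes, 2561 of 2870 alternative values stayed, 305 were weaker and 4 reversed. Within a single cluster Pgr (-0.47) and Hey1 (-0.83) reversed in non-ciliated epithelium and Esr1 (0.24) in smooth muscle. Egr3 in the ciliated class was 4.66 without proximal 2. Its reversal without proximal 4 (fitted at -7.64) rests on 0 CPM in proximal 2 and gives no size. Of 1290 values of genes between clusters 1262 stayed and 28 were weaker, and of 560 marker levels 539 stayed within 1 SD. The ciliated class could not be fitted at resolution 2 or with the title block, nor smooth muscle with at least 500 genes per cell, at resolution 0.5 or with either block.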

Other observations

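The small cluster and the overlaps between classes were chosen after their values were seen. At resolution 2 a cluster of 14 distal cells (7, 4 and 3 per library) carried some genes of early centriole amplification and had 0 counts of others. Deup1, a component of the structure on which new centrioles form, stood at 546 CPM in 9 of the 14 cells, against at most 47.2 CPM in any other epithelial cluster. Cdc20b stood at 364 CPM (8 cells, highest other 5.74), the cyclin O gene Ccno at 162 CPM (6 cells, highest other 8.51), the cyclin Ccna1 at 526 CPM (8 cells, highest other 15.3) and Cdc20 at 566 CPM (5 cells, highest other 6.17). Of these Deup1, Cdc20b, Ccna1 and Cdc20 are leading genes of the cluster itself. Foxn4, Gmnc, Stil and E2f7 had 0 counts in it (highest other 16.1, 24.9, 5.07 and 11.7 CPM). Detection in 1 cell came to 20.2 CPM here, near or above those levels, so the 0 counts do not show lower levels. Mcidas and Plk4 were seen in 1 cell each, at 20.2 CPM (highest other 1.46 and 4.86). Myb and Trp73 stood at 20.2 and 40.4 CPM against up to 109.8 and 190.3 CPM elsewhere. Foxj1 stood at 485 CPM and Ovgp1 at 526 CPM. The cluster met no name and was too small for a test.

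The calcitonin-like receptor partner Ramp1 fell in all 4 classes tested between the regions, by 3.85 on the log2 scale in non-ciliated epithelium, 3.01 in ciliated epithelium, 2.11 in fibroblasts and 1.27 in smooth muscle. Tinagl1 rose in 3 classes and fell in fibroblasts. In total 27 genes were called in 3 or more classes, 22 of them in 1 direction and 18 of them upward, and 6 in 4 classes. Non-ciliated and ciliated epithelium had 43 calls in common, 42 of them in the same direction, non-ciliated epithelium and fibroblasts 66 (61), non-ciliated epithelium and smooth muscle 48 (34), ciliated epithelium and fibroblasts 26 (20), ciliated epithelium and smooth muscle 42 (35), and fibroblasts and smooth muscle 61 (43). Classes of the same library share its free RNA, so these overlaps are not independent.

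T and NK cells numbered 35, 104 and 57 in the distal and 94, 14 and 147 in the proximal libraries, and mesothelial cells 41, 2 and 16 against 0, 8 and 44. Neither was in a planned test. Of the 3 unnamed clusters of the whole data, 1 was led by the antigen presentation genes Cd74 and H2-Aa, and the others had haemoglobin genes among their leading genes.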
